A study of Mus musculus with 21 samples.

How the data were processed

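Chromatin domains were taken from 3e Hi-C of Th2 cells (2 libraries) and R1 ES cells (2 libraries), and expression from poly(A) RNA of EL4 cells with an shLuc hairpin (2 libraries) or an shCTCF hairpin (2 libraries). Groups follow the sample titles. The reads were aligned with Bowtie2 to the mouse build mm9, per the submitters' processing notes. The aligner's version, the domain caller, the gene counter and the annotation release are not given in the sources used here.

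The authors deposited expression as RPKM (reads per kilobase of gene model, scaled to library depth) in a table of 22119 rows with RefSeq transcript identifiers, in which overlapping genes share a row. The authors' deposited table of 435 changed genes repeats these RPKM values. It adds a log2 fold change, a log2 mean CPM, a p-value and an FDR, per the file headers. The tool behind them is not given in the sources used here. The full table numbers the libraries of each hairpin 2 and 3, whereas the table of changed genes numbers the same values 1 and 2, as the titles do. Libraries were therefore used as replicates of their hairpin and are named by the numbers of the full table. The deposited domain lists give chromosome, start and end on a 40 kb grid, called by the authors for each Hi-C library and for the combined libraries of each cell type. All per-sample columns of these files were used.

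For rows with a single transcript the RPKM values of 1 gene in the 4 libraries were searched for whole read numbers. Of 7033 such rows with a mean RPKM of 1 or more, 98.5% gave whole reads in all 4 libraries (relative tolerance 2e-11). Of 2905 rows that join several transcripts, 22.4% did. The reads imply each library's divisor up to a common factor, which was set from the authors' log2 mean CPM. After that the authors' values exceeded those from recovered reads by a median of 0.01 (SD 0.21 over 277 genes). Recovered reads summed to 3332766 and 3895640 (shLuc) and 2765714 and 3671727 (shCTCF) over 9235 rows. They were used to state depth and for alternatives. Applied to simulated RPKM of 1442 rows the search returned all reads up to a common factor within a row. In the data that factor was the smallest that gave a whole length, so recovered reads can be too low.

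Expression was tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes with a trend) on log2(RPKM + 1), with no further normalization and no covariate. Where a symbol had several rows, the row with the highest mean RPKM was used. Genes with a mean RPKM of 1 or more over the 4 libraries were tested (9898). P-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. On simulated data with 200 changed genes among 6646, the test recovered 39% of 1.5-fold, 90% of 2-fold and 96.5% of 4-fold changes. False calls were 9 of 87, 15 of 195 and 15 of 208 calls, in each case a larger share than the threshold of 0.05. The simulation used a dispersion of 0.005, on which these rates depend. No fold is given where both groups rest on 3 reads or fewer. A value of 0 in the table allows up to 3 reads per library, and such limits cover counting error only.

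The 28 gene lists were written before the data were examined, as were the main tests, the named-gene rule and most alternatives. Tests of few-read rows, single deviating libraries and edges at fixed positions were added afterwards. The 21 lists with 5 or more tested members were tested with camera at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation. The rule for named genes took Ctcf, then Gata3, Thy1 and Cd5. It then took the 12 largest rises and 12 largest falls among called genes whose groups did not overlap, and up to 4 called members per list with the smallest p. For a list without called members it allowed up to 2 of its most highly expressed members. Of the genes this rule took, 1 is not reported here. Cohesin subunits, genes of the authors' deposited table and genes in the closing observations were named after their values were seen.

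Domain edges were the distinct starts and ends in a list. An edge was shared when the other list had an edge within 40 kb, and the share is the mean of both directions. Chance came from 1000 circular shifts per chromosome. Cell types were compared by an exact permutation test over the splits of the 4 libraries. In simulated lists that kept 29.8%, 59.7% or 91.0% of the 2887 edges of 1 list, 33.5%, 63.6% and 92.3% were found shared. Coordinates are those of the deposited lists in mm9, written 1-based. Calculations used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and plots matplotlib 3.10.9.

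Gene order along chromosomes came from a RefSeq table of the assembly GRCm38.p6, which placed 9459 of the 9898 tested genes as protein-coding. Since this build differs from mm9, it was used only for which genes are neighbours. For the same reason 2 planned tests that need mm9 gene positions, called genes near domain edges and co-directed change within domains, were not run. Alternatives covered the pseudocount, the expression filter, scaling, a replicate block, the variance trend, duplicate rows, single libraries left out, the edge tolerance, other overlap measures and autosomes only. Others chosen after seeing the data left out rows with under 10 reads or edges at 5, 7 and 43 Mb, or used limma-voom on recovered reads.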

Results

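The series combined chromosome conformation capture, chromatin immunoprecipitation sequencing and RNA sequencing in mouse cells. The parts analysed here are the Hi-C libraries and the RNA libraries of a Ctcf knockdown. CTCF is a zinc-finger protein that binds insulator sites and holds cohesin-mediated chromatin loops. The 3e Hi-C libraries, 2 from Th2 cells (CD4 T helper cells polarised in culture with IL-4) and 2 from R1 embryonic stem (ES) cells, were represented by lists of chromatin domains. The RNA libraries came from EL4, a mouse T lymphoma line. In them, 2 libraries carried a short hairpin against luciferase (shLuc) and 2 a hairpin against Ctcf (shCTCF). The other 13 of the 21 samples, namely 12 ChIP-seq or input libraries and 1 EL4 RNA library without a hairpin in its label, are not analysed here. The RPKM values of the 2 shLuc libraries (headed 2 and 3 in the deposited table) implied divisors of about 5240000 and 6133000 reads, and those of the shCTCF libraries (also headed 2 and 3) about 4347000 and 5769000 reads. One read on a gene model of 1 kb was therefore worth 0.163 to 0.23 RPKM. Nothing in the labels says that libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

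The first question was whether the hairpin lowered its target. Ctcf RNA (transcript NM_181322) fell from 49.9 ± 1.35 RPKM in shLuc to 26.5 ± 0.104 RPKM in shCTCF cells (SD, n = 2 each). The values were 49.0 and 50.9 RPKM against 26.5 and 26.4 RPKM, resting on 981 and 1193 against 441 and 582 reads. The log2 change was −0.89 with a standard error (SE) of 0.08 and an adjusted p of 0.0075 in limma. With only 1 shLuc library in the fit the change was −0.92 or −0.86 and no longer passed (adjusted p 0.15 in both fits). All log2 changes are shCTCF minus shLuc on the log2(RPKM + 1) scale, which understates the change of low genes.

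The second question was which genes changed in shCTCF cells. The labels distinguish no separate hairpins against Ctcf. Effects of lower Ctcf and other effects of the hairpin therefore cannot be told apart here. Among genes of T cells, Ccr4, a chemokine receptor of Th2 cells, fell from 35.5 ± 1.37 to 20.8 ± 1.69 RPKM. Bcl11b, a transcription factor required for T lineage commitment, fell from 26.2 ± 1.52 to 17.2 ± 0.998 RPKM. Genes that rose included Icam4 (an adhesion molecule of red cells), from 4.43 ± 0.606 to 14.9 ± 0.589 RPKM, and Igf1, a growth factor, from 4.52 ± 1.18 to 13.1 ± 0.836 RPKM (SD, n = 2 each). Of 9898 genes tested, 69 rose and 59 fell at a Benjamini-Hochberg adjusted p below 0.05 in limma, and 1398 had an unadjusted p below 0.05. In all 128 called genes the libraries of the groups did not overlap. Such separation held for 44.0% of all tested genes, against 33.3% by chance with 2 against 2 libraries. The absolute log2 change of the called genes had a median of 0.80 and a lower quartile of 0.63.

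Fewer genes passed whenever a library was left out. Such a fit keeps a lone library in a group and has fewer degrees of freedom. Whether the count rests on particular libraries therefore cannot be told from it. Over these fits the log2 change was −0.92 to −0.86 for Ctcf, −0.82 to −0.66 for Ccr4 and −0.64 to −0.52 for Bcl11b. It was 1.44 to 1.67 for Icam4 and 1.15 to 1.59 for Igf1. With all libraries but without the filter on low values, limma called 0 genes (1619 at an unadjusted p below 0.05).

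The 12 largest rises and 12 largest falls among the called genes held 2 kinds of row. In 10 of the 24, 1 group was listed at 0. These were Mir5119, Mir697, Mir1934 and Mir103-2 (at 0 in shLuc) and Snord70, Snord111, Mir194-1, Mir1839, Mir721 and Hist1h2bj (at 0 in shCTCF). Apart from Snord70, whose reads could not be recovered, each rested on 2 or 3 recovered reads over the 4 libraries. No fold is therefore given. These are the smallest whole numbers the search allowed. Hist1h2bj had an implied length of 127 bp, against 393 bp for the histone gene Hist1h2af, so its reads may be a multiple of those recovered. Most of the 10 rows are microRNA precursors or small nucleolar RNAs. The other 14 rows were above 0 in both groups.

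Among these, Fabp4, a fatty acid carrier of adipocytes and macrophages, rose from 6.09 ± 1.06 to 21.8 ± 5.92 RPKM, a log2 change of 1.67 (SE 0.18, adjusted p = 0.0091). Spib, an ETS factor of B cells and plasmacytoid dendritic cells, rose from 1.36 ± 0.107 to 4.84 ± 0.16 RPKM (log2 change 1.31, SE 0.16, adjusted p = 0.0094). Icam4 and Igf1 changed by 1.55 (SE 0.12, adjusted p = 0.0075) and 1.37 (SE 0.16, adjusted p = 0.0091). Fam167b, Dbil5, Apoa2 and the joined row Fbxl13+Lrrc17 also rose, with log2 changes of 1.87, 1.40, 1.33 and 1.34. Dbil5 had 1 read in the shLuc and 12 in the shCTCF libraries. Fam167b had 4 and 1 reads in the shLuc and 20 and 21 in the shCTCF libraries, and Apoa2 4 and 4 against 11 and 15. Of the genes that fell, Ms4a6b, a membrane protein of the MS4A family, went from 16.2 ± 1.74 to 5.96 ± 0.439 RPKM (log2 change −1.30, SE 0.12, adjusted p = 0.0075). Fos and Fosb, subunits of the AP-1 transcription factor, fell by 1.09 (SE 0.13, adjusted p = 0.0094) and 1.24 (SE 0.23, adjusted p = 0.045). Fos went from 11.0 ± 1.58 to 4.61 ± 0.152 RPKM. Mcts2, Gm14718 and Zbtb39 fell by 1.25, 1.13 and 1.10, with Mcts2 at 8 and 10 reads in the shLuc and 1 and 1 in the shCTCF libraries. The size of some of these changes depends on the pseudocount. With 0.1 in place of 1 the log2 changes were 3.16 for Fam167b, 3.37 for Dbil5, −2.02 for Fosb and −2.57 for Mcts2. With limma-voom on recovered reads, a setting chosen after the data were seen, that of Zbtb39 was −1.72. The plot of RPKM per library shows 20 of the named genes.

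**Figure D1:**
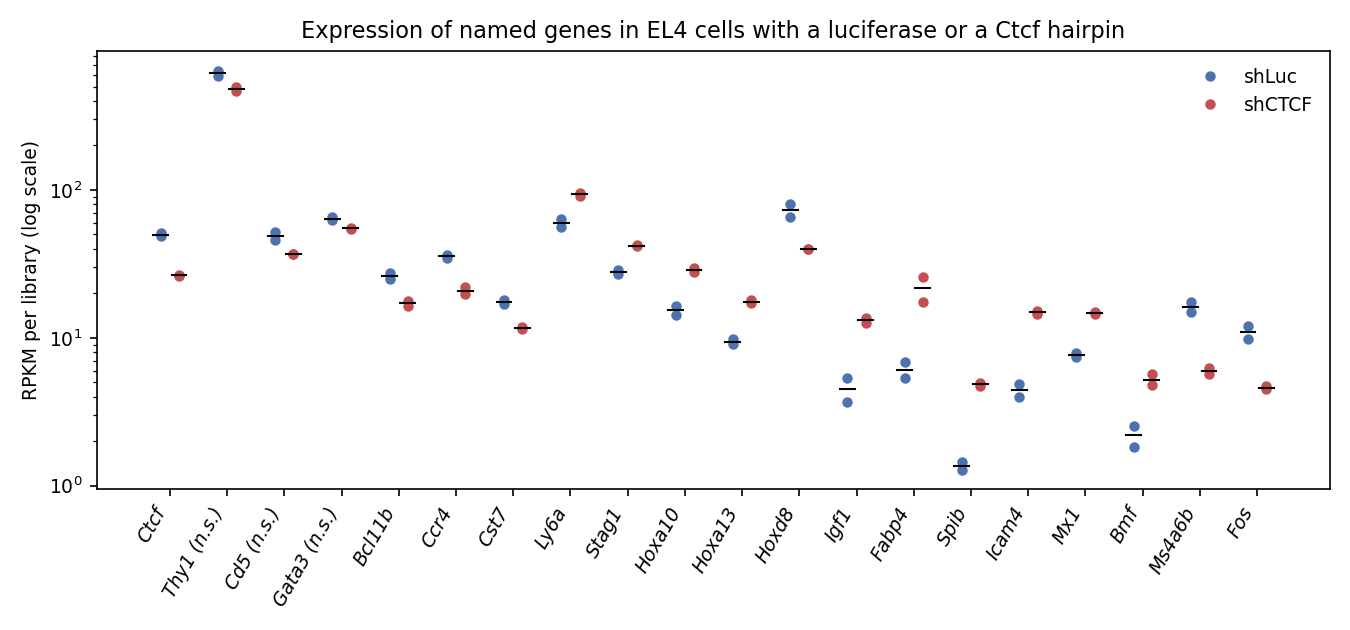
RPKM of 20 genes in each EL4 library on a log axis. Points are single libraries, 2 per group (blue shLuc, red shCTCF), and black lines are group means; n.s. marks genes with an adjusted p of 0.05 or more in limma. Ctcf lies at 49.0 and 50.9 RPKM in shLuc and at 26.5 and 26.4 RPKM in shCTCF cells, and the 3 genes marked n.s. are Thy1, Cd5 and Gata3.

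The study followed T cell genes, and 3 of these did not pass the threshold. Thy1, a surface glycoprotein of T cells, lay at 615 ± 35.4 RPKM in shLuc and 483 ± 21.1 RPKM in shCTCF cells (SD, n = 2 each), with an adjusted p of 0.093 in limma. Cd5, a modulator of T cell receptor signalling, lay at 49.0 ± 4.12 and 36.9 ± 0.371 RPKM with an adjusted p of 0.088. Gata3, the transcription factor that directs Th2 differentiation, lay at 63.9 ± 2.38 and 54.9 ± 0.0928 RPKM with an adjusted p of 0.25. In the authors' deposited table of changed genes, Thy1 had an FDR of 4.3e-04 and Cd5 an FDR of 0.003, and Gata3 was not listed there.

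T cell lists were lower as groups. Of 31 tested T cell receptor and surface molecules, 22 had a negative log2 change. Ly6a (Sca-1, a marker of activated T cells) rose by 0.63 (SE 0.09, adjusted p = 0.016), and 29 members did not pass over all genes. Adjusted over the list alone, 8 were lower and 1 was higher. The list median was −0.18, with an FDR of 1.1e-05 in camera and an adjusted p = 0.56 with an estimated correlation. Of 27 T lineage transcription factors, 20 were lower in value and 1 fell (Bcl11b, log2 change −0.58, SE 0.10, adjusted p = 0.035). Adjusted over the list alone 2 were lower. The median was −0.13 (camera FDR 8.2e-04, adjusted p = 0.56 with an estimated correlation), and −0.08 without the shCTCF library headed 3. Of 8 genes of the Th2 cytokine list, Ccr4 fell (log2 change −0.74, SE 0.09, adjusted p = 0.011) and the other 7 did not pass, also when adjusted over the list alone. That list's median was −0.16 (camera FDR 0.017, adjusted p = 0.58 with an estimated correlation). The median was 0 without the filter on low values, and the FDR was 0.091 without the shLuc library headed 3 and 0.089 without the shCTCF library headed 3.

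Cholesterol and fatty acid synthesis genes were lower by a small amount, and 22 of 25 were negative with a median of −0.12. None passed the threshold for single genes in limma, over all genes or adjusted over the list alone, while 2 highly expressed members, Fasn (fatty acid synthase) and Srebf2 (a sterol-regulated transcription factor), had log2 changes of −0.06 and −0.26. The list had a camera FDR of 8.2e-04 and an adjusted p = 0.56 with an estimated correlation.

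Cytosolic ribosomal protein genes were higher as a group. Of 67 tested, 62 had a positive log2 change and the median was 0.19, with no member past the threshold over all genes or adjusted over the list alone. Rplp1 and Rpl8, the most highly expressed, had log2 changes of 0.28 and 0.09. The camera FDR was 4.3e-12, with an adjusted p = 0.64 with an estimated correlation, and the median was 0.11 under quantile normalization. The medians over the shLuc mean were 0.112 in the shCTCF library headed 2 and 0.28 in the one headed 3. Oxidative phosphorylation genes gave a median of 0.10, and 54 of 66 were positive. Atp5k, an ATP synthase subunit, rose by 0.43 (SE 0.08, adjusted p = 0.042), and adjusted over the list alone 4 were higher. The camera FDR was 5.3e-05, with an adjusted p = 0.77 with an estimated correlation. Without the shCTCF library headed 3 the FDR was 0.35. The medians over the shLuc mean were 0.038 and 0.188 in the shCTCF libraries headed 2 and 3.

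Interferon response genes had a median of 0.20, with 17 of 26 positive. The median was 0.018 over the 11 members with a mean RPKM of 5 or more and 0.13 without the filter, so it rests on members with low values. Mx1, an antiviral GTPase, rose from 7.66 ± 0.386 to 14.7 ± 0.395 RPKM (log2 change 0.86, SE 0.10, adjusted p = 0.0095), and adjusted over the list alone 3 genes were higher. The list's camera FDR was 0.029 and the adjusted p = 0.56 with an estimated correlation. The FDR was above 0.05 without the shLuc library headed 3 (0.091) and without the shCTCF library headed 2 (0.27). Thus none of the 7 lists called with the preset correlation, 3 higher and 4 lower, held with an estimated one. The estimated form takes its degrees of freedom from 4 libraries, so few lists could pass and the loss decides little. Estimates lay below the preset 0.01 for the T cell receptor, cholesterol and interferon lists (−0.025, −0.012 and −0.033). Correlation among members therefore does not explain the loss of those calls. Estimates were above it for the T lineage, Th2, oxidative phosphorylation and ribosomal protein lists (0.048, 0.069, 0.36 and 0.48).

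**Figure D2:**
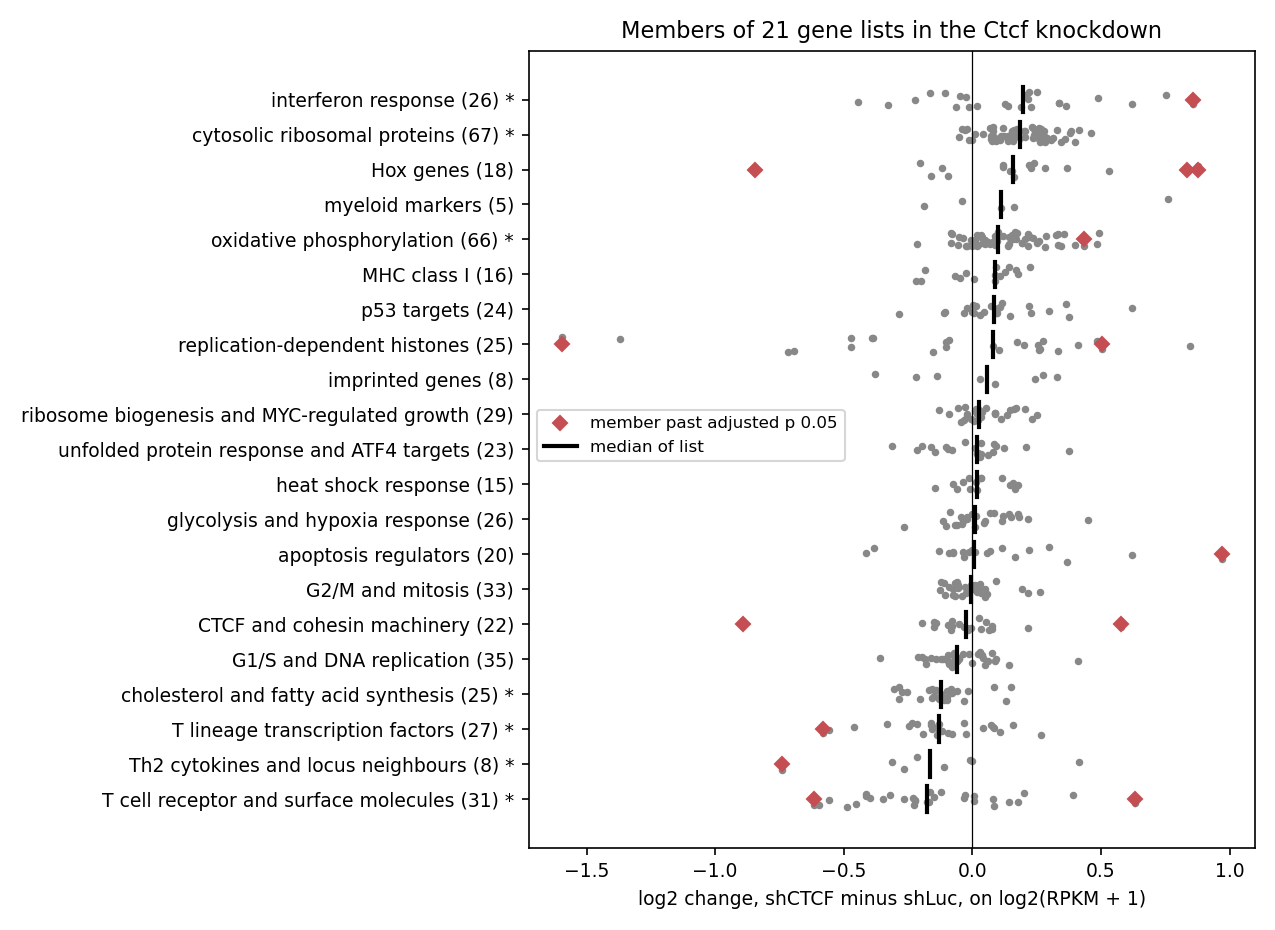
Log2 change (shCTCF minus shLuc, on log2(RPKM + 1)) of each tested member of 21 gene lists, with the number of members in parentheses. Grey points are members, red diamonds those with an adjusted p below 0.05 in limma, black bars list medians, and an asterisk marks a camera FDR below 0.05 with the preset correlation. List medians run from −0.18 in T cell receptor and surface molecules to 0.20 in the interferon response.

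The other lists were not called in camera. Among 18 tested Hox genes, Hoxa10 and Hoxa13 rose by 0.88 (SE 0.10, adjusted p = 0.0091) and 0.83 (SE 0.10, adjusted p = 0.0094), while Hoxd8 fell by 0.85 (SE 0.11, adjusted p = 0.011). Adjusted over the list alone 2 were higher and 1 lower, and the list's FDR was 0.084. The list's median was 0.16. It was 0.26 without the shCTCF library headed 2 but 0.069 without the one headed 3, so its size rests largely on the latter library. In the CTCF and cohesin list (22 tested, camera FDR 0.36, 1 higher and 1 lower adjusted over the list alone), Ctcf fell and Stag1, a cohesin subunit, rose from 27.9 ± 1.40 to 42.1 ± 0.41 RPKM (log2 change 0.58, SE 0.08, adjusted p = 0.02). The cohesin subunits Rad21, Smc1a, Smc3 and Stag2 had log2 changes of −0.03, 0.07, 0.08 and −0.02. Bmf, a pro-apoptotic BH3-only protein, rose by 0.97 (SE 0.17, adjusted p = 0.042) among 20 apoptosis regulators (camera FDR 0.67), of which 4 were higher and 2 lower adjusted over the list alone. Of 25 replication-dependent histone genes, Hist1h2af rose by 0.50 (SE 0.09, adjusted p = 0.047) and Hist1h2bj was the low row named above. This list had a median of 0.08 and a mean of −0.09, with a camera FDR of 0.76, and 3 genes were higher and 3 lower adjusted over the list alone. Its median turned to −0.079 without the shLuc library headed 3, −0.14 without the shCTCF library headed 3 and −0.079 without the filter on low values. Reads of these near-identical histone genes can be split between copies. The libraries were of poly(A) RNA, and how fully these capture histone transcripts was not tested.

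No member passed over all genes in the lists of p53 targets (24 tested, median 0.08, FDR 0.076, 4 higher adjusted over the list alone) and of G1/S and DNA replication (35 tested, median −0.06, FDR 0.078, 0 adjusted over the list alone). The same held for G2/M and mitosis (33 tested, median −0.01, FDR 0.68), ribosome biogenesis (29 tested, median 0.03, FDR 0.36) and the unfolded protein response (23 tested, median 0.02, FDR 0.67). It held also for glycolysis and hypoxia (26 tested, median 0.01, FDR 0.67, 1 higher adjusted over the list alone), heat shock (15 tested, median 0.02, FDR 0.67) and MHC class I (16 tested, median 0.09, FDR 0.76). Imprinted genes (8 tested, median 0.06, FDR 0.76) had 1 gene lower adjusted over the list alone. In 4 of the lists just named (G2/M, ribosome biogenesis, unfolded protein response and heat shock) and in MHC class I, 0 genes passed when adjusted over the list alone. With 1 library left out, the medians of G2/M, ribosome biogenesis, the unfolded protein response, glycolysis and imprinted genes turned sign. Those of G1/S, p53 targets and MHC class I came as close to 0 as −0.025, 0.049 and 0.012. That of p53 targets was 0.022 without the filter on low values, and that of heat shock 0.00066 under quantile normalization.

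Markers of other cell types were mostly below the expression filter. Of 25 myeloid markers 5 were tested (median 0.11, FDR 0.39, 1 higher adjusted over the list alone), with a median of 0.033 to 0.24 when 1 library was left out. Fewer than 5 were tested, so no list test was made, for B cells (3, with Spib higher), NK and cytotoxic cells (4), fibroblasts (3), ES cells (1), erythroid cells (1) and epithelial or neural cells (1). Adjusted over the list alone, 1 gene was higher in each of the B cell and ES cell lists and 1 lower in each of the NK and fibroblast lists. Of the NK list, Cst7, a cathepsin inhibitor of cytotoxic cells, fell by 0.55 (SE 0.10, adjusted p = 0.042). None of the 58 clustered protocadherin genes was tested.

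The authors' deposited table lists 435 rows, 214 higher and 221 lower in shCTCF cells. Its smallest FDR belongs to Traf6, an adaptor of innate receptor signalling, with a log2 fold change of −1.05 (FDR 4.7e-24), followed by Ctcf with −0.93 (FDR 9.7e-24) and Ccr9, a homing receptor of gut T cells, with −0.88 (FDR 1.5e-23). Traf6 and Ccr9 are named here by their rank in the authors' deposited table. Of its genes, 416 were among the 9898 tested here, and all 416 had the same sign in limma. Both called 107 genes, while 21 were called in limma and absent from the authors' deposited table. That table was made from the same 4 libraries and is not independent evidence.

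The Hi-C lists addressed how domain structure differs between the T helper and the stem cells. Chromatin domains are stretches of a chromosome whose loci contact each other more often than loci outside. ES domains covered more of the genome, 2123 and 2141 Mb in the 2 ES libraries against 1998 and 1941 Mb in the 2 Th2 libraries. The number of domains did not separate the cell types, with 1828 and 1833 in ES and 1961 and 1689 in Th2 cells. The median domain size was 920 kb in both ES libraries and 680 and 840 kb in the Th2 libraries. Edges, the distinct domain starts and ends, numbered 2887 and 2990 in ES and 2587 and 2568 in Th2 cells. With 4 libraries an exact two-sided permutation test cannot give a p below 0.333, and it gave 0.333 for coverage and median size and 1 for the number. The authors' combined lists held 2042 ES and 1941 Th2 domains with median sizes of 840 and 760 kb. The largest listed domain of the combined Th2 list lay at chromosome X, 108400001 to 120240000 (mm9), and that of the ES list at chromosome X, 58400001 to 65920000.

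Libraries of a cell type shared more edges than libraries of different types. Within 40 kb, 78.2% of edges were shared between the 2 ES libraries and 75.6% between the 2 Th2 libraries. The 4 pairs across cell types shared 52.6% to 53.9%. The mean difference was 23.5 percentage points, the largest of the 3 possible splits of the 4 libraries (exact permutation p = 0.333, the smallest possible). The combined lists shared 55.8%. Circular shifts of one list along each chromosome gave 11.1% to 12.2% on average, and no pair was reached in 1000 shifts (permutation p = 0.001, the smallest they can give). The share of domains with a reciprocal overlap of 80% or more was 66.1% and 61.3% within and 30.4% to 31.4% across cell types. On chromosome X the sharing was 66.5% within and 43.4% across types, the lowest of the 20 chromosomes in both.

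**Figure D3:**
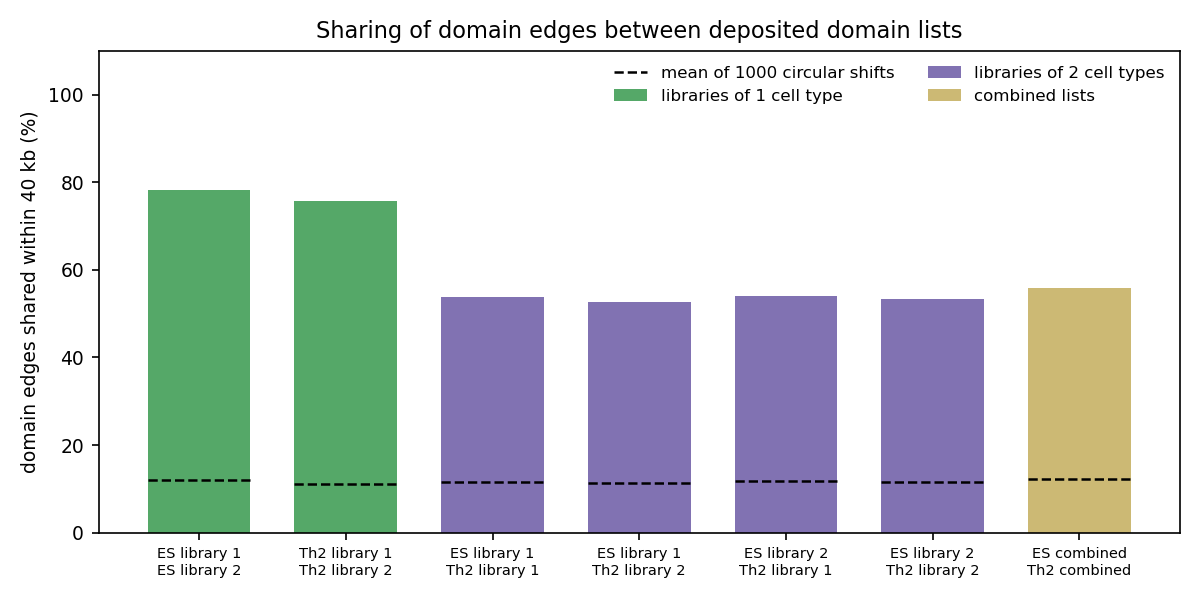
Percentage of domain edges shared within 40 kb for each pair of domain lists, as the mean of both directions. Bars are single pairs, coloured by whether both libraries are of 1 cell type, of 2 cell types or are the authors' combined lists; dashed lines are the mean of 1000 circular shifts. The 2 pairs within a cell type stand at 75.6% and 78.2%, and the 4 pairs across types at 52.6% to 53.9%.

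Of 1873 edges found in both Th2 libraries, 998 (53.3%) lay within 40 kb of an edge in each ES library, and 342 (18.3%) had no ES edge within 200 kb. Of 2264 edges found in both ES libraries, 1119 (49.4%) were also in each Th2 library, and 439 (19.4%) had no Th2 edge within 200 kb. Of 905 domains listed in both Th2 libraries with start and end each within 40 kb, 205 (22.7%) held edges of both ES libraries inside. The reverse held for 245 of 1008 ES domains (24.3%). The Th2 domain at chromosome 2, 84280001 to 90160000 (5.88 Mb), held 5 edges in each ES library, and that at chromosome 15, 53840001 to 57360000 (3.52 Mb), also held 5 in each. The ES domain at chromosome X, 137600001 to 144200000 (6.6 Mb), held 3 edges in each Th2 library. Genes in these regions are not named, since no mm9 annotation was used here. This 200 kb rule and these regions were chosen after the lists were examined.

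Edges at fixed positions recurred across chromosomes. An edge at exactly 7 Mb was listed on 15 to 17 of the 20 chromosomes and one at exactly 43 Mb on 14 to 16, in each of the 6 lists. Circular shifts gave at most 7 chromosomes at any position. An edge at exactly 5 Mb was listed on 4 to 9 chromosomes, and it exceeded the shifts in ES library 2 (9), Th2 library 2 (8) and the combined Th2 list (8). These edges count as shared in both cell types.

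**Figure D4:**
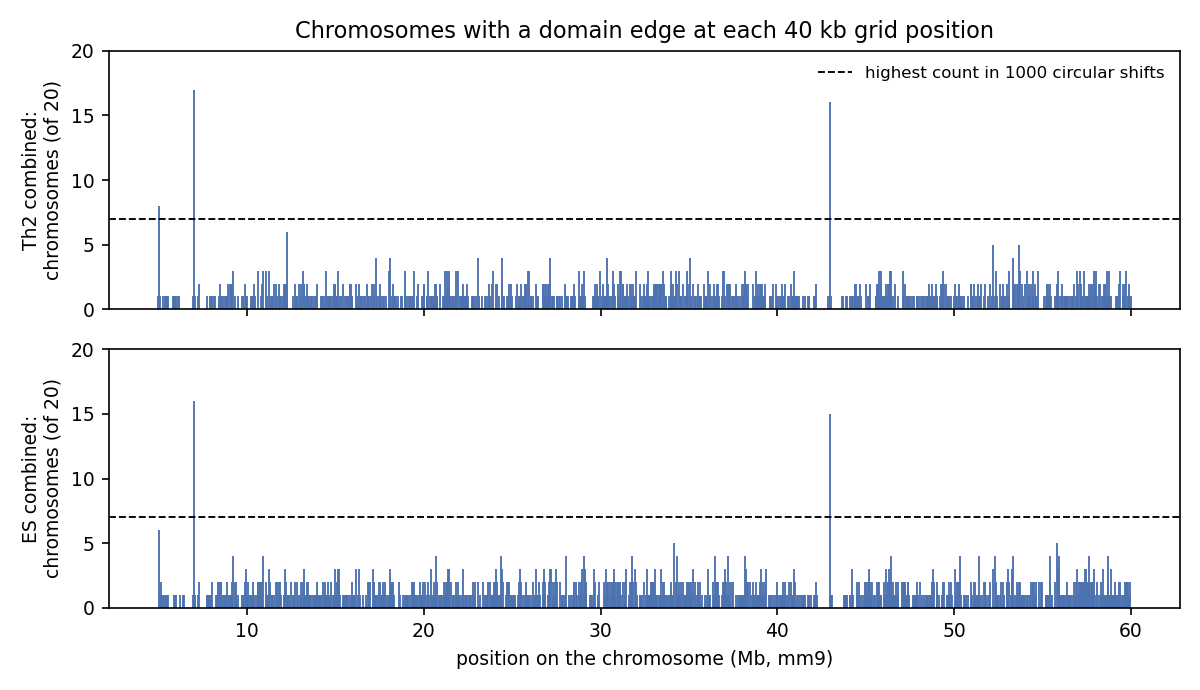
Number of chromosomes (of 20) with a domain edge at each position of the 40 kb grid, from the chromosome start to 60 Mb (mm9), in the authors' combined Th2 (top) and ES (bottom) lists. Dashed lines are the highest count in 1000 circular shifts, 7 in both lists; the peaks at 7 Mb reach 17 and 16 chromosomes and those at 43 Mb 16 and 15.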

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

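Settings based on recovered reads and on edges at fixed positions were chosen after the data were seen. Whether same-numbered libraries share a day or batch is not known. No label ties them, so the numbers were not taken to pair the libraries (2 pairs). The deviations of same-numbered libraries correlated at 0.16, and with the replicate block limma called 294 genes higher and 213 lower. Of the other settings, 0 and 0 genes were called without the filter on low values (1619 at an unadjusted p below 0.05), where Ctcf kept a log2 change of −0.89 but did not pass. Without the trend 33 and 27 were called, and 202 and 173 with limma-voom on recovered reads. The cause was not tested. Leaving out single libraries gave 0 to 49 higher and 0 to 35 lower genes, and Ctcf changes of −0.92 to −0.86. In these fits the lone library is assumed to vary like the other group. Of 583 combinations of 40 named genes and settings, the gene no longer passed in 170 and newly passed in 4 (Thy1 and Cd5, each with the replicate block and with limma-voom). Most of these genes were chosen as called, so their direction was not open.

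With an estimated correlation, which has little power at 2 libraries per group, 0 lists were called higher and 0 lower. Without single libraries 2 to 4 lists were higher and 3 to 5 lower. The replicate block ended the interferon call (FDR 0.063) and changed no other list. Lists newly called were G1/S under quantile normalization (0.046), Hox genes and p53 targets without the shCTCF library headed 2 (0.0055 and 0.038), and the CTCF and cohesin list and ribosome biogenesis without the shLuc library headed 2 (both 0.04).

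On autosomes only, domains covered 1872 Mb in Th2 and 2021 Mb in ES cells, since fewer chromosomes were counted. The median ES size was 900 kb on autosomes. Leaving out 1 library moved the Th2 mean number of domains between 1689 and 1961, its median size between 680 and 840 kb and its coverage between 1941 and 1998 Mb. For ES cells the ranges were 1828 to 1833, 920 to 920 kb and 2123 to 2141 Mb. No domain was below 100 kb, so that filter moved nothing.

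Edge sharing within types, across types and between combined lists was 54.7%, 32.0% and 34.7% at 20 kb, which on this grid asks for the same position. It was 80.9%, 59.3% and 61.4% at 80 kb. By reciprocal overlap of domains it was 63.7%, 30.9% and 34.4%, and by base-pair Jaccard index 87.7%, 77.6% and 79.8%. Without edges at 5, 7 and 43 Mb the sharing across types was 52.8%. Without single libraries it was 52.99% to 53.9% across and 75.6% to 78.2% within types. In every setting sharing was higher within than across types. Gene positions limit what could be tested: called genes near edges and co-directed change within domains were not run, nor were edgeR and DESeq2, planned for the case of deposited counts. With 2 libraries per group, 39% of simulated 1.5-fold changes were recovered at the simulated dispersion of 0.005.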

Other observations

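The genes below were chosen after their values were seen, and so were the tests of few-read rows, single libraries and fixed positions. The immediate-early genes were looked up because Fos and Fosb were among the largest falls. Of 16 tested, only these 2 fell and none rose in limma. Of these genes, the authors' deposited table lists Fos and Fosb as lower and Btg2 as higher (FDR 0.017). Egr1, a zinc-finger factor induced with Fos, lay at 30.7 ± 0.921 RPKM in shLuc and 32.5 ± 0.506 RPKM in shCTCF cells (SD, n = 2 each), with an adjusted p of 0.76. Junb and Jund, which pair with Fos proteins, had log2 changes of 0.20 and 0.04, and Ier2 and Zfp36 0.04 and −0.06. The median over the 16 genes was 0.12.

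Other genes fell in limma and were named after their values were seen. Ccr9, a homing receptor of gut T cells, went from 106.5 ± 2.87 to 58.0 ± 4.41 RPKM (log2 change −0.87, SE 0.08, adjusted p = 0.0075). Il21r, the receptor of interleukin 21, went from 26.7 ± 2.63 to 13.5 ± 0.69 RPKM (log2 change −0.94, SE 0.10, adjusted p = 0.0091), and Itgal, the LFA-1 alpha chain, fell by 0.45 (SE 0.08, adjusted p = 0.046). Traf6 went from 22.6 ± 0.242 to 11.0 ± 0.222 RPKM (log2 change −0.98, SE 0.09, adjusted p = 0.0075), beside −0.89 (SE 0.08) for Ctcf itself.

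Neighbouring genes were tested for change in common, a hypothesis about local effects of lower Ctcf. Over 4923 neighbouring, non-overlapping protein-coding pairs the log2 changes correlated at 0.0827 across genes, which are not independent replicates, above the highest of 1000 shuffles (0.0508; permutation p = 0.001, the smallest they can give). The difference between the 2 shLuc libraries gave 0.149 over the same pairs, and that between the 2 shCTCF libraries 0.0182. Since a difference between control libraries gave more, a correlation of this size can arise without the knockdown. The planned condition, a value above both within-group differences, was therefore not met. The shCTCF difference lay within its shuffles (highest 0.0452), so the 2 within-group differences disagree. Without pairs sharing the first 3 letters of the symbol, the correlation of log2 changes was 0.0682. An effect of the knockdown is thus neither shown nor excluded. Among called genes, 4 neighbouring pairs were both called, against a mean of 0.625 and a highest value of 4 in 1000 shuffles. In 2 of them both genes rose, Apip with Ehf (log2 changes 0.67 and 0.91) and Htatsf1 with Vgll1 (0.86 and 1.21). In the other 2 they went apart, Itgal with Zfp768 (−0.45 and 0.70) and Tnnt3 with Mrpl23 (1.23 and −0.92).

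Among 147 tested microRNA and small nucleolar RNA rows, 14 were called. Counting noise in rows with few reads is a candidate explanation for those with under 10. Of 72 tested rows with under 10 recovered reads, 9 had reads in both libraries of 1 group and none in the other. Placing the same reads by library depth alone gave 6.78 such rows on average in 1000 draws, at most 12 in the central 95% and at most 17 in any. The observed number thus lies within what depth alone gives, and the few-read rows may reflect counting noise. A biological change in single rows of this kind stays open at 2 or 3 recovered reads, the smallest numbers the search allowed. How well libraries of poly(A) RNA represent such small RNAs was not tested either.

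The higher ribosomal protein and oxidative phosphorylation lists were set against transcript length and a single deviating library. Short transcripts were higher in general, and the shortest of 5 equal classes of genes (median 914.5 bp) had a median log2 change of 0.0809, against −0.0121 in the longest class. Oxidative phosphorylation genes differed from genes of like length and expression by −0.0259 (95% bootstrap interval −0.0602 to 0.0126), so this rise may follow length. For ribosomal proteins that difference was 0.0584 (0.00534 to 0.0926), but only 76.1% had a length, too few for the test, so length and an effect of the knockdown cannot be told apart there. In the lower shCTCF library the list medians were 0.112 (ribosomal) and 0.038 (oxidative phosphorylation), above the differences of 0.00109 and 0.00814 between shLuc libraries but below those of 0.17 and 0.164 between shCTCF libraries. With 2 libraries per group, a single deviating library and an effect of the knockdown thus cannot be told apart in either list.

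Domain edges at 7 and 43 Mb were weighed as a product of the domain calling. Over the 6 lists the smallest number of chromosomes with such an edge was 14, above the highest of the shifts (7), in both cell types. Other edges were scarce around them. Within 600 kb of 43 Mb, 3 other edges were listed in each combined list, against medians of 30 (ES) and 25 (Th2) elsewhere. Windows of equal length from 7 Mb on would put an edge at 79 Mb, which was listed on at most 2 chromosomes, so the tables argue against that form. The count of 14 is the observation itself, so a fixed position grid in the calling cannot be told apart from other causes by it. No biological explanation was tested, and the domain caller is not given in the sources used here.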
